A study of Mus musculus with 5 samples.

How the data were processed

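The samples were sciatic nerves of mice at 5 weeks of age, 3 with Acly deleted by Mpz-driven Cre and 2 controls. Per the labels' protocols, RNA was purified from the nerves, polyA RNA was selected, cDNA was primed with random hexamers and the libraries were sequenced on an Illumina instrument. Whether the library kit or the counting kept the strand is not given in the sources used here. The submitters' processing notes name HISAT2 (no version given), featureCounts 1.5.0-p3, DESeq2 1.20.0 and the builds GRCm38 and mm10, without the order or settings of these tools.

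The authors deposited a table of raw read counts for 54532 genes in 5 libraries, whole numbers without normalization. Its column names hold short codes that were matched to the sample titles by their letters for knockout and wild type and their numbers. The authors' deposited table of the comparison gives log2 fold changes of knockout over wild type, p-values and adjusted p-values for 27096 genes. Its adjusted p is exactly 1 for 9458 genes, which may stand for values that were not computed. A further 17 columns of per-sample or mean values in it were not used. Gene coordinates come from the count table. Of its genes, 54495 are in GENCODE vM21, and 98.3% of these have the same start and end there, so coordinates are on GRCm38.

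Depth was 16181104 to 19496947 counts per library. With that depth, 3 counts in a library equal 0.154 to 0.185 CPM. The 10 most abundant genes took 14.4% and 14.1% of counts in the controls and 12.2%, 10.8% and 10.9% in cKO 1, cKO 2 and cKO 3. Depth is thus similar across libraries, and the small number of mice limits precision more than counting does for genes above a few CPM.

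Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr filter (minimum count 10; 16476 genes kept), and a quasi-likelihood F test of genotype on all 5 libraries, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are scaled by TMM-adjusted library sizes. For named genes with 1 to 3 counts in the controls together, the ratio is given with an exact binomial counting interval. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over 32 lists, and again with the correlation estimated per list and with fry. Of 483 list symbols, 480 matched exactly 1 row. Ahsp matched none, and for Ddit3 and Atp5o the row with more reads was used.

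The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Acly, the 12 genes that rose and the 12 that fell with the largest log2 fold changes among called protein-coding genes with an average log2 CPM of at least 1 and libraries that do not overlap, and up to 4 members of each list by smallest adjusted p, or up to 2 where none was called. Other genes are marked in the text as chosen after their values were seen. The alternatives were RLE and upper-quartile scaling, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, a replicate block, a test against a fold change of 1.5, robust dispersions and each library left out in turn. Removal of a smooth trend on gene length and GC content (splines with 5 degrees of freedom, GC from the reference for 99.9% of tested genes) and a covariate for libraries with Y-linked transcripts were chosen after seeing the data.

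The fits were tested on simulated data for this comparison of 3 against 2 libraries, with 16476 genes, 10 draws and 200 genes changed in each draw. Both the trended and the gene-wise dispersions of the real data were used, because the result depends on which is chosen. With trended dispersions edgeR recovered 43.6% of 2-fold and 83.8% of 4-fold changes, and 4.28% of its calls were false. With gene-wise dispersions it recovered 20.9% and 74.5%, and 6.38% were false, slightly above the nominal 5%. DESeq2 had 9.33% and 22.0% false calls under the 2 models, and limma-voom 4.49% and 5.17%. Camera had a p under 0.05 in 2.1% of 1000 unchanged lists of 20 genes under either model. The simulated genes were independent, so this does not test camera on correlated genes. Python 3.11.15 and matplotlib 3.10.9 drew the plots.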

Results

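RNA was measured in the sciatic nerve of mice that lack ATP citrate lyase (ACLY) in Schwann cells, the glia that wrap and myelinate the axons of peripheral nerve. ACLY cuts citrate in the cytosol and so supplies acetyl-CoA for the synthesis of fatty acids and cholesterol. The knockout (Acly cKO) was made by crossing a floxed Acly allele to a Cre line driven by the promoter of Mpz, the gene of the main protein of peripheral myelin. Nerves were collected at 5 weeks of age from 3 cKO mice and 2 control mice, with 1 library per mouse. Total gene counts were 17297953 in control 1, 16181104 in control 2, 17713079 in cKO 1, 19496947 in cKO 2 and 18926275 in cKO 3. The single comparison asks how loss of ACLY in Schwann cells alters the transcripts of the whole nerve, which also holds axons, fibroblasts, vessels and immune cells.

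Acly (ENSMUSG00000020917) is on chromosome 11 of GRCm38, from 100476353 to 100528000, on the minus strand. Its level was 372 and 360 CPM, a read count scaled to library size, in control 1 and control 2, and 70.3, 135 and 104 CPM in cKO 1, cKO 2 and cKO 3. The mean was 366 ± 8.90 CPM in controls (SD, n = 2) and 103 ± 32.4 CPM in cKO nerves (SD, n = 3). In edgeR's quasi-likelihood test the log2 fold change was -1.83 (SE 0.26, Benjamini-Hochberg adjusted p = 0.0135), so each library stood on the side its label gives. The count covers all exons of the gene, and the deleted part is not given in the sources used here. The call was lost without control 1 (adjusted p = 0.135), without control 2 (0.132) or without cKO 3 (0.0654), while the log2 fold change stayed between -2.07 and -1.61 over the 5 fits that leave out a library.

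Of 16476 genes tested, 688 were higher and 640 lower in cKO nerve, 1328 in all at an edgeR adjusted p under 0.05. In each of the 1328 the libraries of the groups did not overlap. Chance gives this for 20% of genes with groups of 3 and 2. Genes picked by a small p lean to it by construction, so it adds no separate support. Library cKO 1 stood apart from the other cKO libraries. The SD over genes of its log2 difference was 0.829 to cKO 2 and 0.788 to cKO 3, against 0.386 between cKO 2 and cKO 3 and 0.442 between the controls. Without cKO 1 the count rose to 5032 of 16317 tested genes (2381 higher, 2651 lower), and 1324 of the 1328 genes were among them. Counts of list members called without cKO 1, given below, are to be read against that larger share of all genes. The count was 650 without cKO 2, 390 without cKO 3, 80 without control 1 and 28 without control 2, where a lone control is assumed to vary like the cKO libraries. Of the 92 called genes named beside Acly, 66 lost their call without control 1, 77 without control 2, 25 without cKO 2 and 37 without cKO 3. In the authors' deposited table, 1989 genes had an adjusted p under 0.05, and 1320 of the 1328 were among these with the same sign.

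**Figure D1:**
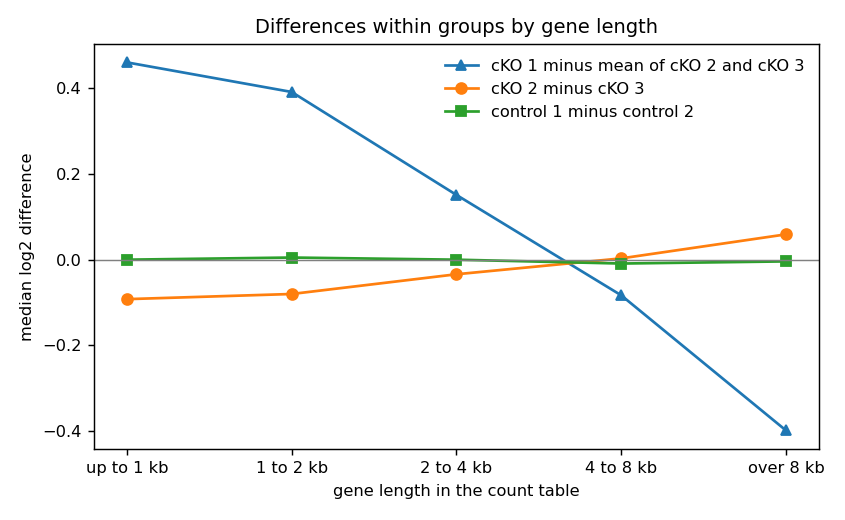
Median log2 difference between libraries of the same group by gene length in the count table, for cKO 1 against the mean of cKO 2 and cKO 3 (triangles), cKO 2 against cKO 3 (circles) and control 1 against control 2 (squares). The first line runs from 0.46 in genes up to 1 kb to -0.40 in genes over 8 kb, while the control line stays between -0.009 and 0.005.

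The largest increases were in genes close to silent in control nerve. Shh, a secreted morphogen, rose from 2.06 ± 0.488 CPM to 169 ± 9.98 CPM (SD, n = 2 and n = 3; log2 fold change 6.36, SE 0.21, edgeR adjusted p = 0.000691). Slc17a8, a vesicular glutamate transporter, rose by 7.26 on the log2 scale to 63.7 CPM, the EGF-family ligand gene Btc by 6.36 to 62.3 CPM and the semaphorin Sema4f by 6.73 to 74.4 CPM. Ucn2, a peptide of the corticotropin-releasing factor family, rose by 6.85, the WNT inhibitor gene Wif1 by 6.55 and Nr1h4, the bile acid receptor FXR, by 6.16. Klk9 rose by 6.86, but it is 1 of a family of similar kallikrein genes and it overlaps a gene on the opposite strand, and the strand setting of the counting is not given. Some of these genes had 1 to 3 reads in the controls together, so their ratios are wide. Olig1, a transcription factor gene, was 839 times higher (95% counting interval 150 to 33200), and Fgf5, a growth factor gene, 258 times (71.3 to 2140). The protease gene Tmprss13 was 65.4 times higher (22.2 to 319), and the phosphatase gene Ptpn5 63.6 times (17.4 to 528). These intervals cover counting error only.

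Among the genes that fell most, Cntn1, an adhesion molecule of axons and glia, went from 17.9 ± 1.504 to 0.679 ± 0.261 CPM (SD, n = 2 and n = 3; log2 fold change -4.69, SE 0.32, edgeR adjusted p = 0.00169). Cyp2j13 had a log2 fold change of -4.71, with the caution that reads of similar cytochrome P450 genes could be shared. Pla2g5, a secreted phospholipase, had a log2 fold change of -3.84, Dlk1, a NOTCH-family surface protein, -3.58, and Spint1, a protease inhibitor, -3.53. The melanin-concentrating hormone receptor gene Mchr1 stood at -3.58, Dpysl5 at -3.47, the synaptic adhesion gene Nlgn1 at -3.41 and Npy6r at -3.38. Foxi2 stood at -3.29, Plk5 at -3.20 and Fam81a at -3.20. Plk5 was the most abundant of these in control nerve, at 102 ± 23.1 CPM, against 11.0 ± 4.88 CPM in cKO nerve.

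**Figure D2:**
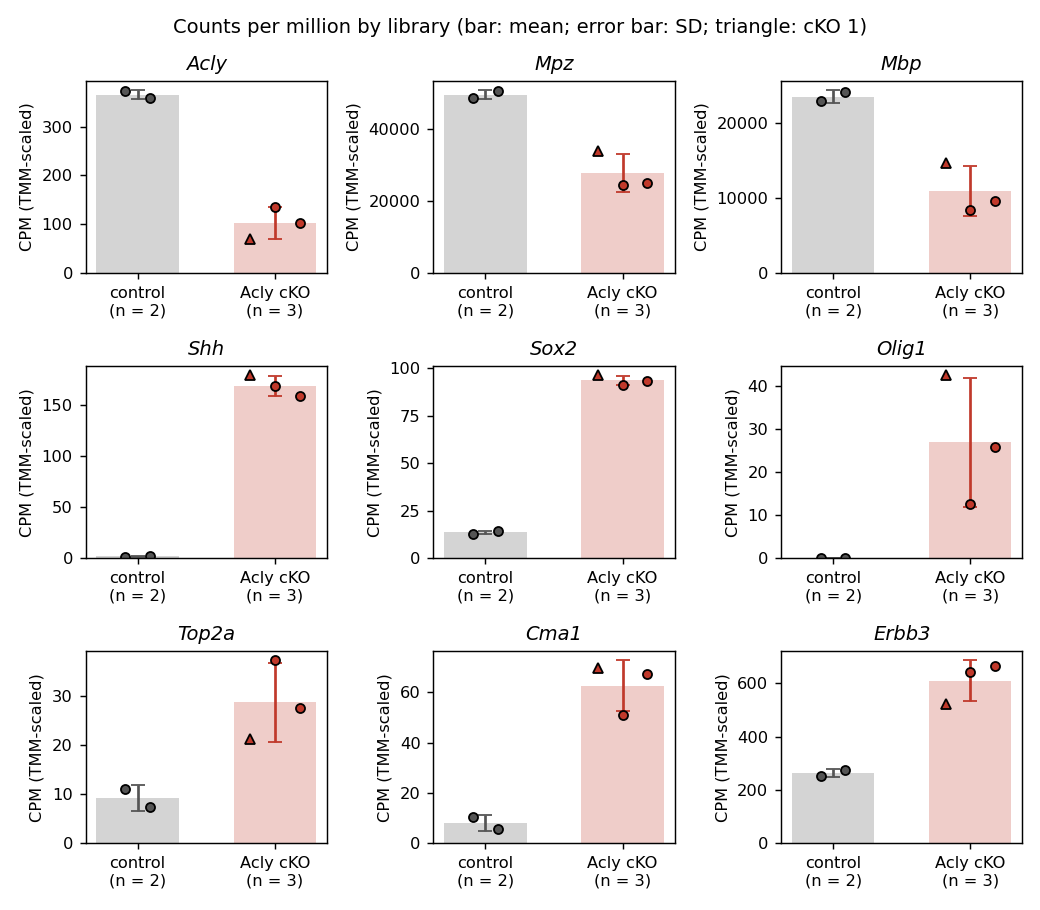
CPM of 9 genes in each library, with bars for the mean and error bars for the SD of control (n = 2) and Acly cKO (n = 3) nerves. Points are libraries, the triangle is cKO 1, and Acly lies between 70.3 and 135 CPM in cKO nerves against 360 and 372 CPM in controls.

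Most genes of the repair Schwann cell program, which Schwann cells switch on after nerve injury, rose. Of 19 measured members 14 rose, 0 fell and 5 did not pass (16 and 2 adjusted over the list alone), with a median log2 fold change of 3.10. Beside Shh, Gap43, a growth-associated protein, rose from 3.39 to 173 CPM (5.67 on the log2 scale), the transcription factor Runx2 from 3.66 to 43.7 CPM (3.57) and Sox2, which holds Schwann cells in an immature state, from 13.6 to 93.5 CPM (2.78). Sox2 lies inside Sox2ot on the same strand, which also rose, by 0.86. The set test camera gave adjusted p = 2.17e-13 with a preset correlation between genes, and adjusted p = 0.376 with an estimated correlation. The list's median against the control mean was 3.48 in cKO 1, 2.90 in cKO 2 and 2.94 in cKO 3. Without cKO 1, 16 members were called higher and 2 lower. The list median was 2.99 without control 1 and 3.23 without control 2. Fewer members were called in these fits, which rest on a lone control.

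Myelin structure genes fell in part. Of 21 measured members 8 fell and 1 rose (11 and 2 adjusted over the list alone), and the median log2 fold change was -0.55. Prx, a protein of the outer myelin membrane skeleton, fell from 7610 ± 245 to 3792 ± 104 CPM (SD, n = 2 and n = 3; log2 fold change -1.005, SE 0.13, edgeR adjusted p = 0.00898). The enzymes of myelin sphingolipids Fa2h and Ugt8a had log2 fold changes of -1.21 and -1.29, and the myelin proteolipid gene Pllp had -1.18. Mpz and Mbp, chosen after their values were seen, lay at the threshold. Mpz had a log2 fold change of -0.84 with an edgeR adjusted p of 0.05, just under the threshold, and a range of adjusted p from 0.0523 to 0.396 in the alternatives that lost the call. Mbp had -1.10 with an adjusted p of 0.0508. The camera test gave adjusted p = 0.00617, and adjusted p = 0.425 with an estimated correlation. Library cKO 1 had the highest Mpz and Mbp of the cKO nerves. Without cKO 1 the test called 13 members lower and 4 higher, without cKO 2 it called 5 lower, without cKO 3 it called 3, and without either control it called 0. The list median was -0.575 without control 1 and -0.53 without control 2.

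Regulators of the Schwann cell lineage moved less evenly. Of 16 measured regulators of myelination, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0889). Pou3f1, a factor of promyelinating Schwann cells, rose by 2.37 on the log2 scale from 53.6 to 276 CPM, and the neuregulin receptors Erbb3 and Erbb2 by 1.21 and 0.65. Nab1, a co-factor of EGR2, had a log2 fold change of -1.12. Egr2 and Sox10, chosen after their values were seen, had log2 fold changes of 0.20 (edgeR adjusted p = 0.534) and 0.22 (0.420). With cKO 1 left out the test called 7 regulators higher and 2 lower, and camera called that list upward (adjusted p = 0.0304, and adjusted p = 0.551 with an estimated correlation). Among 14 measured genes of immature and Remak Schwann cells, 6 rose and 1 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.0906). These included Sox2, the low-affinity neurotrophin receptor gene Ngfr (3.10), Gfap (3.81) and the endothelin receptor gene Ednrb (2.60). Ngfr, Gfap and Sox2 are also in the repair list. In the immature and Remak list the test called 8 higher and 5 lower without cKO 1, 3 higher without control 1 and 1 higher without control 2.

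No list of lipid genes passed camera, which tests for a shift in a single direction, with all libraries. Fry, read for changes in either direction, gave adjusted p = 1.47e-05 for fatty acid synthesis and desaturation. It gave 0.000598 for lipid efflux and LXR targets, 0.00612 for cholesterol synthesis and 0.00923 for citrate and acetyl-CoA handling. For fatty acid oxidation and lipid uptake it gave 0.0306. Most other lists also passed fry read this way. Of 25 measured cholesterol synthesis genes 1 rose and 0 fell (3 and 1 adjusted over the list alone), with a median log2 fold change of 0.12 and camera adjusted p = 0.142. The one was Lss, lanosterol synthase, which rose by 0.71 on the log2 scale. Hmgcr, which encodes the rate-limiting enzyme, had 0.06 (edgeR adjusted p = 0.865) and Hmgcs1 -0.20 (0.479), both chosen after their values were seen. Of 19 genes of fatty acid synthesis and desaturation 1 rose and 2 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.142). The acyl-CoA synthetase gene Acsl3 rose by 1.13, while the elongase genes Elovl6 and Elovl7 had log2 fold changes of -1.14 and -1.40. Fasn and Acaca, chosen after their values were seen, had -0.07 (edgeR adjusted p = 0.908) and -0.64 (0.120).

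Of 16 genes of citrate and acetyl-CoA handling 1 rose and 1 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.0836). Acss2, which makes acetyl-CoA from acetate, rose from 102 ± 9.63 to 160 ± 10.4 CPM (SD, n = 2 and n = 3; log2 fold change 0.65, SE 0.13, edgeR adjusted p = 0.0373). It overlaps Ggt7 on the opposite strand, which rose by 1.02. The pyruvate dehydrogenase kinase gene Pdk2 had a log2 fold change of -0.71. Of 14 genes of lipid efflux and LXR targets 2 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.954): Apoe rose by 0.71 and Soat1 by 0.84, and the sterol transporter gene Abcg1 had -1.69. Of 17 genes of fatty acid oxidation and lipid uptake 0 passed (1 and 4 adjusted over the list alone; camera adjusted p = 0.0906), with Pdk4 at -1.18 (edgeR adjusted p = 0.0634). Without cKO 1 the test called 9 of 25 cholesterol synthesis genes higher and 3 lower, 5 of 19 fatty acid synthesis genes higher and 8 lower, and 5 of 14 lipid efflux genes higher and 4 lower. It then called 1 of 16 citrate and acetyl-CoA genes higher and 6 lower, and camera called that list downward (adjusted p = 0.0456, and adjusted p = 0.551 with an estimated correlation). Of the 17 oxidation and uptake genes it called 1 higher and 7 lower without cKO 1. Camera called the oxidation and uptake list downward without cKO 3 (adjusted p = 0.0317, and adjusted p = 0.462 with an estimated correlation).

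Mast cell transcripts rose in cKO nerve. Of 9 measured members 8 rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 2.95. The chymase gene Cma1 rose from 8.05 ± 3.30 to 62.5 ± 10.1 CPM (SD, n = 2 and n = 3; log2 fold change 2.95, SE 0.31, edgeR adjusted p = 0.00513), and Mcpt4 by 2.94. The tryptase genes Tpsb2 and Tpsab1 rose by 3.03 and 3.21, and reads could be shared among these similar proteases. Hdc, the enzyme of histamine synthesis, chosen after its value was seen, had 1.80 (adjusted p = 0.0512). The list passed camera (adjusted p = 1.47e-09), with adjusted p = 0.376 with an estimated correlation. The test called 9 members without cKO 1, 3 without control 1 and 0 without control 2. The list median was 3.415 without control 1 and 2.58 without control 2.

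Of 18 macrophage genes 3 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00527, and adjusted p = 0.425 with an estimated correlation). The phagocyte receptor gene Trem2 rose by 2.26 on the log2 scale, the fractalkine receptor gene Cx3cr1 by 2.20 and the protease gene Ctss by 1.18, while the scavenger receptor gene Cd163 had -1.35. The pan-macrophage markers Csf1r and Adgre1, chosen after their values were seen, had 0.10 (edgeR adjusted p = 0.820) and 0.32 (0.676). Both lay below the list median of 0.55, and 15 of the 18 log2 fold changes were above 0, so these markers do not stand for the list. Without cKO 2 the macrophage list missed the threshold of camera (adjusted p = 0.0711). The test called 11 macrophage genes higher and 1 lower without cKO 1, 2 higher without cKO 3 and 0 without either control, where the list median was 0.605 and 0.57. Of 13 chemokine and complement genes 2 rose and 0 fell (6 and 0 adjusted over the list alone), Cxcl10 by 3.59 and Ccl2 by 2.07. Camera gave adjusted p = 0.0242 for that list, 0.124 without cKO 2, and adjusted p = 0.425 with an estimated correlation. The test called 7 of them higher and 1 lower without cKO 1, 1 higher without cKO 3 and 0 without either control, with medians of 0.52 and 0.37. Neutrophil genes had 1 of 2 measured called, the receptor gene Csf3r at 1.33 (1 adjusted over the list alone; camera adjusted p = 0.0889). None of 4 measured lymphocyte genes (0 adjusted over the list alone; camera adjusted p = 0.142) and none of 15 interferon-stimulated genes (0 adjusted over the list alone; camera adjusted p = 0.619) passed edgeR's test. The interferon median was 0.72 in cKO 1, -0.21 in cKO 2 and -0.44 in cKO 3 against the control mean. Leaving out cKO 1, the test called 3 interferon-stimulated genes lower, and camera called the list downward (adjusted p = 0.0378, and adjusted p = 0.551 with an estimated correlation). Without control 2 camera called the lymphocyte list (adjusted p = 0.0134) and the neutrophil list (0.0405) upward, with 0 members called in either (adjusted p = 0.575 and 0.502 with an estimated correlation). The test called, with cKO 1 left out, 2 of 5 lymphocyte genes and both neutrophil genes higher.

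Of 20 measured cell proliferation genes 7 rose and 0 fell, and 13 did not pass (16 and 0 adjusted over the list alone). All 20 log2 fold changes were above 0, with a median of 1.17. Ccnb1 rose by 1.92, Aurkb by 1.72, Top2a by 1.63 and Ccna2 by 1.48, genes of mitosis and DNA replication. Camera gave adjusted p = 1.47e-09, and adjusted p = 0.376 with an estimated correlation. The test called 15 members without cKO 1 and 0 in each of the 4 fits that left out another library. In those 4 fits the list median was 0.94 to 1.30. Camera gave adjusted p = 3.73e-08 without cKO 2, and 0.522 with an estimated correlation. Without cKO 3 it gave 1.06e-09, and 0.42 with an estimated correlation. Of 14 immediate early genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), among them Egr3 by 2.92, Fos by 2.80, Egr1 by 1.55 and Junb by 1.04. For them camera gave adjusted p = 9.43e-05, and adjusted p = 0.376 with an estimated correlation. The test called 7 of them without cKO 1, 3 without cKO 3, 2 without control 1 and 1 without control 2, with a list median of 0.52 to 0.77 over these fits.

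In the lists of other nerve cell types most measured genes did not pass, from 7 of 10 perineurial genes to all 14 adipocyte genes. For comparison, 1328 of all 16476 tested genes were called. All 14 measured adipocyte genes were below 0, with a median log2 fold change of -1.01 and 0 called (0 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.000116, and adjusted p = 0.514 with an estimated correlation). Their median was -1.79 in cKO 1, -1.21 in cKO 2 and -0.43 in cKO 3 against the control mean. All 13 endothelial genes were below 0, with a median of -0.57 and 1 called, Cldn5 at -0.74 (1 lower adjusted over the list alone; camera adjusted p = 0.00104, and adjusted p = 0.425 with an estimated correlation). Without cKO 1, the test called 10 adipocyte, 11 endothelial, 6 perineurial, 8 pericyte and smooth muscle and 8 sensory neuron genes lower. Of 10 perineurial genes 1 rose and 2 fell (1 and 6 adjusted over the list alone): Crabp2 rose by 1.05, and Moxd1 and the integrin gene Itgb4 had -1.57 and -1.12. The perineurial list had a camera adjusted p of 0.0170, 0.0575 without control 1, and adjusted p = 0.425 with an estimated correlation.

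Of 13 pericyte and smooth muscle genes 1 rose and 1 fell (1 and 7 adjusted over the list alone), Mcam by 1.57 and Pdgfrb at -0.56. Camera gave adjusted p = 0.0490, from 0.0616 to 0.110 without control 1 or without any 1 of the cKO libraries, and adjusted p = 0.425 with an estimated correlation. Of 20 fibroblast and collagen genes 3 rose and 2 fell (3 and 3 adjusted over the list alone). The matrix genes Tnc and Postn rose by 5.02 and 1.37, and Lox and Mfap5 had -1.57 and -0.84. The signs of this list differ by measure, with a median of -0.12, a mean of 0.09 and camera downward (adjusted p = 0.748). Of 8 skeletal muscle genes 0 rose and 1 fell, Actn3 at -2.24 (0 and 1 adjusted over the list alone; camera adjusted p = 0.223). None of 5 erythroid genes passed edgeR's test (0 adjusted over the list alone; camera adjusted p = 0.770), and without cKO 3 camera called that list upward (adjusted p = 0.00584, and adjusted p = 0.462 with an estimated correlation). Among fibroblast and collagen genes edgeR called 6 higher and 6 lower without cKO 1. Of 11 measured genes of the sensory neuron list, 1 rose and 2 fell (2 and 4 adjusted over the list alone). Which cells of the nerve held these transcripts was not measured. The tubulin gene Tubb3 rose by 3.995, and the neurofilament gene Nefh and the sodium channel gene Scn9a had -1.74 and -3.09. Camera gave adjusted p = 0.0332 for that list, 0.0809 without cKO 2, 0.0771 without control 2, and adjusted p = 0.607 with an estimated correlation.

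Among stress and energy genes, 2 of 16 endoplasmic reticulum chaperone genes rose and 0 fell (2 and 0 adjusted over the list alone), Sdf2l1 by 1.28 and Manf by 0.72. Camera gave adjusted p = 0.0380, and adjusted p = 0.514 with an estimated correlation. Leaving out any 1 library other than cKO 1 ended that call (adjusted p from 0.0543 to 0.154) and left 0 members called. Without cKO 1 the test called 10 of 16 higher, and the camera adjusted p was 0.000883, and adjusted p = 0.551 with an estimated correlation. The list's median was -0.03 in cKO 1, 0.56 in cKO 2 and 0.35 in cKO 3. Of 15 integrated stress response genes 0 rose and 1 fell, the serine synthesis gene Phgdh at -0.91 (3 and 3 adjusted over the list alone; camera adjusted p = 0.342). Among 13 p53 targets Aen rose by 0.87 and Sesn1 had -0.68 (1 and 1 adjusted over the list alone; camera adjusted p = 0.349). Among 14 oxidative stress genes Srxn1 rose by 1.35 and Gstm1 had -0.62 (1 and 5 adjusted over the list alone; camera adjusted p = 0.120). When cKO 1 was left out, the test called 5 integrated stress response genes higher and 3 lower, 3 p53 targets higher and 3 lower, 3 oxidative stress genes higher and 7 lower, and 5 of the nuclear respiratory chain genes lower. With all libraries, none of 17 nuclear genes of the respiratory chain (camera adjusted p = 0.632) and none of 12 mitochondrially encoded genes (0.770) passed edgeR's test, with 0 in each adjusted over the list alone. Sex-linked genes split the libraries within both groups, with Y-linked transcripts in control 1 and cKO 1 and Xist in the other 3. None of the 5 differed between genotypes (0 adjusted over the list alone; camera adjusted p = 0.748).

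**Figure D3:**
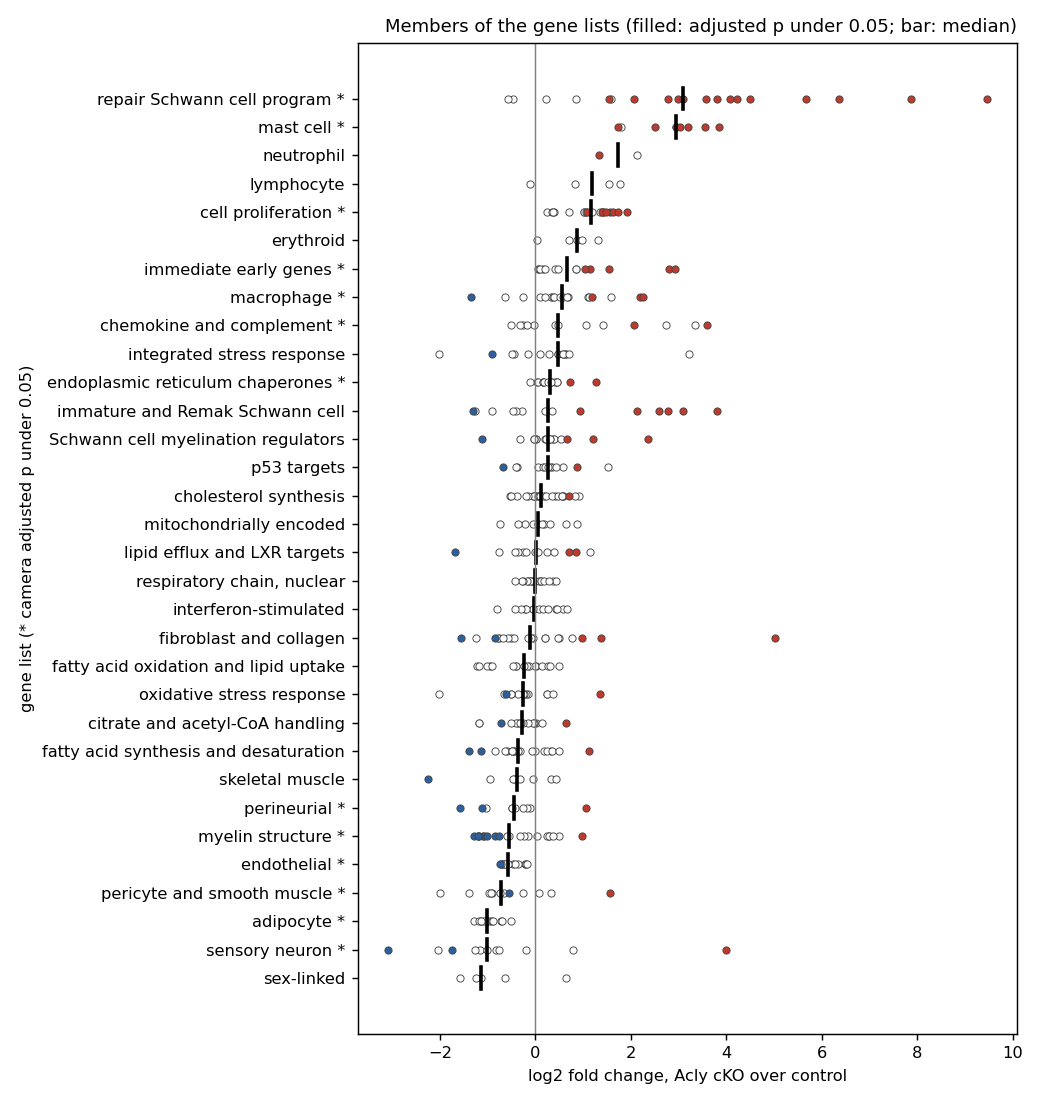
Log2 fold change (Acly cKO over control) of each measured member of 32 gene lists, with filled points for an edgeR adjusted p under 0.05, vertical bars for list medians and stars for a camera adjusted p under 0.05. Medians run from 3.10 in the repair Schwann cell program to -1.01 in the adipocyte and sensory neuron lists, and to -1.14 in the sex-linked list.

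In all, camera called 13 of 32 lists, 7 upward and 6 downward. The self-contained test fry, read for a shift in a single direction, called 10, of which 7 were among the 13. Fry alone called myelination regulators (fry adjusted p = 0.0273), immature and Remak Schwann cell (0.0183) and oxidative stress genes (0.0336). Camera alone called the macrophage (fry adjusted p = 0.058), perineurial (0.0725) and pericyte and smooth muscle lists (0.113). It alone also called the adipocyte (fry adjusted p = 0.169), endoplasmic reticulum chaperone (0.201) and sensory neuron lists (0.369). Camera with an estimated correlation between genes called 0. The 0 does not rest on the correlation alone, as that setting also tests on the residual degrees of freedom of the fit. The chemokine and complement list had an estimated correlation of -0.003, below the preset 0.01, yet its camera p went from 0.00755 to 0.0663. With n = 3 and n = 2 mice, the fit to all libraries has 3 residual degrees of freedom, and 3894 genes had an unadjusted p under 0.05.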

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

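The count of 1328 genes moved little with RLE scaling (1330), upper-quartile scaling (1304), a stricter filter (1292), limma-voom (1211) and robust dispersions (1276), and was 1934 without a filter. It was 1995 with DESeq2, 494 when tested against a fold change of 1.5 and 28 to 5032 with 1 library left out. The length and GC trend removal gave 2190 and the Y-linked covariate 1778, both chosen after seeing the data. In simulation DESeq2 had more false calls than edgeR. It also recovered more 2-fold changes, 46.6% and 46.9% under the trended and gene-wise models against 43.6% and 20.9%. Only 200 genes were changed per draw, so the simulation cannot tell which of the added DESeq2 calls are false. The 1.5-fold test asks for more by construction, and 33 of the 92 called genes named beside Acly lost their call in it. The cause of the other shifts was not tested, beyond fewer libraries. The share of higher calls was 51.8%, and 71.2% without control 1 and 78.6% without control 2.

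Acly kept its direction and, outside the fits with a library left out, its call. Its log2 fold change ran from -2.07 to -1.61 over those fits, and -1.80 without control 1, -1.86 without control 2 and -1.83 without cKO 3 had an adjusted p above the threshold, with fewer samples. The 13 lists became 0 with an estimated correlation, and with 1 cKO library left out from 8 (without cKO 2) to 15 (without cKO 1). The Y-linked covariate gave 10 lists, 10 of them among the 13. The length and GC trend removal gave 14, with 12 among the 13. Of the 92 called genes named beside Acly, 66 lost the call without control 1, 77 without control 2, 25 without cKO 2 and 37 without cKO 3. Signs turned without control 1 for Kdm5d (9.46; -2.59 without control 2), Uty (8.87; -2.25) and Egr2 (-0.004; 0.42), without cKO 1 for Fasn (0.16; -0.27 without cKO 2), and without cKO 2 for Hmgcr (-0.04; 0.19 without cKO 1), Csf1r (-0.105; 0.26) and Adgre1 (-0.042; 0.63). None of these 7 was called in the full comparison, and the Y-linked pair turned because control 1 is the only control with Y-linked transcripts.

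Libraries of both groups share the numbers 1 and 2, and the labels give them only a number in common. Those numbered 1 also share Y-linked transcripts and those numbered 2 Xist, so the block follows these too. With that replicate block on 4 libraries, 1085 genes passed (549 higher, 536 lower), 843 of them among the 1328, and 16 lists. The deviations of same-numbered libraries from their group means correlated at 0.133, and at 0.073 without 5 sex-linked genes.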

Other observations

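The tests below were chosen only after the results were seen, except that the genes of the second mast cell list and the bound on their median were set before. A further list of 8 genes, taken as made by Schwann cells at most stages, had a median log2 fold change of 0.26. EdgeR called 2 of them higher and 0 lower. The list is not independent of those above, as Sox10, Erbb3, Plp1 and Cdh19 are also members there. Foxd3, a neural crest factor, rose from 105 ± 5.79 to 248 ± 17.0 CPM (SD, n = 2 and n = 3; log2 fold change 1.24, adjusted p = 0.00549), and Erbb3 rose by 1.21, while S100b had -0.69 (adjusted p = 0.0873). The calls of Foxd3 and Erbb3 are both lost without control 1 (adjusted p = 0.130 and 0.178) or without control 2 (0.118 and 0.155), and that of Erbb3 without cKO 3 (0.0556). Protein-coding genes were also grouped by the stem of their symbols, and none of 348 tests over 174 families passed Fisher's exact test after adjustment. The lowest was for Aldh genes, with 5 of 19 lower where 0.82 was expected (Fisher's exact test, one-sided, p = 0.00101, adjusted p = 0.142).

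Library cKO 1 lay apart from the other cKO libraries. Over its difference from their mean, the Spearman correlation across genes was -0.366 with gene length and 0.361 with GC content, against -0.011 and -0.086 for the control pair, and 80 ribosomal protein genes were higher by a median of 1.22. Removing the trend took away 12.1% of the variance, so a length-linked difference in RNA or library quality may be part of the cause. Yet the SD, with the sex-linked genes left out, stayed at 0.722 against 0.414 for the control pair. This argues against that trend as the whole cause. A difference shared by both genotypes between animals with and without Y-linked transcripts is argued against by a rho of 0.018 between the 2 differences. Dbp was 200 CPM and Nr1d1 97.6 CPM in cKO 1, against 26.4 to 36.1 and 8.24 to 27.2 CPM in the other libraries. Malat1 was 218 CPM and mt-Nd5 469 CPM in cKO 1, against 813 to 992 and 1375 to 1614 CPM in the others. Time of collection, severity and an effect of sex within cKO mice were not tested.

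Mast cell transcripts were higher in every cKO library. Fat or muscle carried along with the cKO nerves is argued against, as the higher of the medians of those lists was -0.38. As a hypothesis, the cKO nerve may hold a larger share of mast cell RNA. In a second list of 12 mast cell genes the median log2 fold change was 1.498, which met the bound of 1 and taken alone would favour it. A further condition, over 50% of genes called higher, was first left out and was applied after the output was seen, and it was not met, with 25% called (Mrgprb1 at 2.88, Slc18a2 at 1.54 and Il1rl1 at 1.46). In simulation edgeR recovered 20.9% to 43.6% of 2-fold and 74.5% to 83.8% of 4-fold changes. The median of 1.498 lies between these sizes, so low power may hold the share called down. Those rates are for 200 changed genes drawn at random from all tested genes, so they are not the power for this list. It holds genes of low level, such as Cd200r3 at 0.214 CPM in controls. That condition therefore cannot decide, and the question stays open. These 3 calls are each lost without control 1 or without control 2, where the log2 fold changes were 3.66 and 2.38 for Mrgprb1, 1.78 and 1.33 for Slc18a2 and 1.565 and 1.35 for Il1rl1.

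Of 21 myelin genes 8 fell and 1 rose, while 14 of 19 repair genes rose and 0 fell. A lower share of Schwann cells as the only change would raise the markers of other cell types alike. The endothelial median was -0.57 while mast cell genes rose, which argues against it as the only change. The endothelial call was lost in camera with an estimated correlation (adjusted p = 0.425). A lower share beside changes in other cell types cannot be told from these lists. The quality of cKO 1 is argued against as the cause, since without it the smaller ratio of the new to the old list medians was 0.942. Beyond the share of Schwann cells no biological explanation was tested for this pattern, and a response of Schwann cells to the genotype or to a change in axons stays open. The sensory neuron list, whose transcripts were not traced to axons, had a median log2 fold change of -1.01, with Nefh at -1.74 (edgeR adjusted p = 0.0138) and Tubb3 at 3.995.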
